A study of Homo sapiens with 8 samples.

How the data were processed

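m6A immunoprecipitation sequencing (MeRIP-seq) was carried out by the submitters on BCPAP cells, with input and anti-m6A immunoprecipitate libraries from control and METTL3 knockdown cells. Per the labels' protocols, poly(A) RNA was purified from total RNA and fragmented with magnesium, incubated with an m6A antibody, and made into dUTP-marked cDNA libraries for paired-end sequencing. Samples were grouped by the genotype and antibody labels into 4 groups of 2 libraries, 8 libraries in all. The 2 knockdown libraries of each type carry the titles sh1 and sh3, so they are not repeats of 1 construct. Nothing in the labels says whether the 2 libraries of a group came from separate cultures.

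The submitters' processing notes name fastp, HISAT2, HOMER, ChIPseeker, StringTie and edgeR and the builds GRCh38 and hg38, without saying which step each was used for. The caller of the differential peaks, its filters, and whether replicates or the sh1 and sh3 libraries were pooled are not given in the sources used here. The comparison itself is the authors': 1 deposited table of 10987 peaks with position, genomic span, gene, region annotation, annotation terms and statistics. The p-value of each peak is the authors', per the file headers. The log2 fold change of m6A enrichment is the authors' deposited value, and its sign matched the up or down label in all 10987 peaks. The score behind the FDR was deposited by the authors as the log10 of a false discovery rate, per the file headers, and was raised back to the linear scale here. The reference condition of the fold change is not named in the header, and it was read as knockdown relative to control. If it were the reverse, every direction given here would turn around. The deposited FDR was a median of 1.99 times the Benjamini-Hochberg value recomputed over these peaks, which were therefore not taken as all the peaks the authors tested. The largest p in the table was 0.692 and the smallest absolute log2 fold change 0.0468.

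Genomic spans include introns, with a median of 389 bases, quartiles of 181 and 1316 and a largest span of 308813. Some peaks overlap: the 10987 peaks form 10024 separate places. There were 306 peaks without a gene name, which stayed out of analyses by gene. Of 9774 peaks whose gene name matched a symbol of the RefSeq annotation of GRCh38.p14, 9178 (93.9%) overlapped the bounds of that gene and 1 lay on another chromosome. Of 3754 peaks annotated to exons, 735 name an exon of another gene identifier than the peak's own, and 458 peaks were assigned to pseudogenes. Annotation terms were not used here for 1220 peaks (11.1%) in the gene ontology column and 5 in the KEGG column, so these peaks enter neither the terms nor their background. The table has no strand, so a peak of a gene and of its antisense partner cannot be told apart.

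A peak was called at a deposited FDR under 0.05, with no threshold on the fold change. For analyses by gene, 1 peak per gene name was kept, that with the smallest p. The share of lower peaks was given with a 95% Clopper-Pearson interval and a two-sided exact binomial test against 50%; intervals cover counting error only, and peaks are not independent replicates. Regions, gene lists and terms were compared with two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 3 regions, over the 42 tests of 21 lists, and over all tests of each term source. The comparison of lower against higher within terms was adjusted only over the terms of a source that had already passed. Terms needed at least 10 genes in the table, and the background was all genes in the table with a term of that source, 4991 for gene ontology and 2251 for KEGG. Zinc finger genes were counted by the start of their symbols. The list adjustment over the list alone recomputed Benjamini-Hochberg values from the authors' p-values of its members. Counts over all peaks use the deposited FDR, which is larger than a recomputed value, so part of each difference between the paired counts can come from the measure. The gene lists, calling threshold and rule for named genes were fixed before the data were examined. The rule took the 10 largest decreases and 10 largest increases among called genes, 1 peak per gene, without clone, predicted or pseudogene names (107 called genes were left out for such names), and up to 4 called members of each list with the largest absolute change; a list member that was not called could be named with its values only. It gave 64 genes, of which some are not reported here. Genes named for terms, genes named only in the closing part, the list members that were not called (METTL14, ZC3H13, VIRMA, METTL16, FTO, MYC and STEAP2), YTHDF1, HNRNPA2B1, BRD3, CREBBP and the extra peaks of CCND1, ITGB1, TGFB1, U2AF1, CD70, CREBBP, FTO, MYC and KIF7 were chosen after their values were seen.

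Analyses used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The list test was tested on simulated data over the 7081 named genes: lists with 50% lower members passed p under 0.05 in 79% of 100 lists of 10 genes, 93% of lists of 20 and 100% of lists of 40, and unplanted lists in 6%, 3% and 2%. This p was not adjusted over the 42 tests, and several lists had fewer than 10 measured members. The power behind the adjusted list results is therefore lower. The simulation also drew members at random and gave each gene an independent call. Members of the real lists can share region, depth and number of peaks, so these rates need not hold for them. The table holds no counts, so the depth of each library, the counting error behind each fold change and the spread between libraries are unknown. Alternatives tried were p under 0.01, an absolute log2 fold change of at least 1, 1 peak per gene, centring on the median of all peaks, all peaks whatever their p, a recomputed Benjamini-Hochberg adjustment, 1 peak per overlapping place, leaving out ribosomal protein genes and pseudogenes, and keeping peaks within the RefSeq bounds of their gene, which also leaves out peaks whose gene name did not match a RefSeq symbol. The design fixed in advance also held METTL3 levels, gene expression, m6A against expression, and the sequence motif at peaks. The first 3 need values per library or an expression table and were not run on this table, and the motif was not analysed here because no genome sequence was used.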

Results

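N6-methyladenosine (m6A) was profiled by immunoprecipitation and sequencing of fragmented poly(A) RNA from BCPAP cells, a line derived from a papillary thyroid carcinoma. The cells either carried a knockdown of METTL3, the catalytic subunit of the nuclear m6A methyltransferase, or served as controls. There were 8 libraries in 4 groups of 2, namely control input, control immunoprecipitate, knockdown input and knockdown immunoprecipitate. The knockdown libraries are titled sh1 and sh3, with 1 library of each title per library type. The question put by the submitters was which transcripts differ in m6A once METTL3 is depleted. The values analysed were those of the authors' deposited table, which lists 10987 m6A peaks on 7372 gene identifiers, each with a log2 fold change, a p-value and a false discovery rate (FDR). All scores and fold changes below are therefore the authors', and no replicate spread can be attached to them. Read counts were not analysed here, so the depth of each library is unknown. Coordinates are on GRCh38. The column header does not name the reference condition, and "lower" and "higher" below read the fold change as knockdown relative to control. METTL3 itself has 0 peaks in the table, and its transcript level was not analysed here.

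The first comparison asked in which direction m6A peaks changed after METTL3 knockdown. Whether the deposited FDR covers variation between libraries of a group is not known, so a small value need not mean agreement between sh1 and sh3. At an FDR under 0.05, 1883 of the 10987 peaks in the authors' deposited table (17.1%) were called as different between knockdown and control. Of these, 1167 peaks were lower and 716 were higher in the knockdown, so that 62.0% of the called peaks were lower (95% Clopper-Pearson interval 59.7 to 64.2%). The called changes were mostly small. Lower peaks had a median log2 fold change of -0.45 in the authors' deposited table, equal to 0.733-fold, with quartiles of -0.74 and -0.30. Higher peaks had a median of 0.47, equal to 1.38-fold, with quartiles of 0.30 and 0.85 in the authors' deposited table. An exact two-sided binomial test against an equal split gave p = 2.01e-25, although peaks are not independent replicates. With 1 peak per named gene, 994 genes were lower and 585 were higher among 7081 genes. The excess of lower peaks lay among the small changes: of the called peaks with an absolute log2 fold change of at least 1, 165 were lower and 149 higher (52.5% lower, exact binomial p = 0.397). The median of all peaks was -0.24, and after this shift was subtracted, which makes every lower value smaller and every higher value larger without a new test, 1015 called peaks were lower and 867 higher (53.9% lower).

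The second comparison concerned where in the transcript the changed peaks lay, using the region that the authors' annotation gives to each peak. This label need not give the place in the main transcript, since spans include introns and a TWIST2 peak labelled 3' UTR covers 61139 bases. The 3' UTR held 42.7% of all peaks. Of the 3' UTR peaks 21.8% were called, against 16.8% of 5' UTR peaks and 11.5% of peaks in other exons. Peaks in 3' UTRs carried most of the losses: 745 of them were lower and 279 higher, so that 72.8% of the called 3' UTR peaks were lower (95% Clopper-Pearson interval 69.9 to 75.5%). Called 5' UTR peaks were split almost evenly, with 223 lower and 203 higher (52.3% lower, interval 47.5 to 57.2%). Among peaks in other exons, 199 were lower and 234 higher (46.0% lower, interval 41.2 to 50.8%). The plot of called peaks by region shows these counts. The 3' UTR thus held 63.8% of all lower peaks and 39.0% of all higher peaks (odds ratio 2.77, Fisher's exact test, Benjamini-Hochberg adjusted p = 2.53e-25 over the 3 regions). The 5' UTR held 19.1% of the lower and 28.4% of the higher peaks (odds ratio 0.597, adjusted p = 4.16e-06), and other exons held 17.1% and 32.7% (odds ratio 0.423, adjusted p = 1.69e-14). After the median shift was subtracted, 62.4% of the called 3' UTR peaks, 44.8% of the 5' UTR peaks and 42.7% of the exon peaks were lower. Among called peaks with an absolute log2 fold change of at least 1, the regions no longer differed past the threshold (3' UTR odds ratio 1.20, adjusted p = 0.882).

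**Figure D1:**
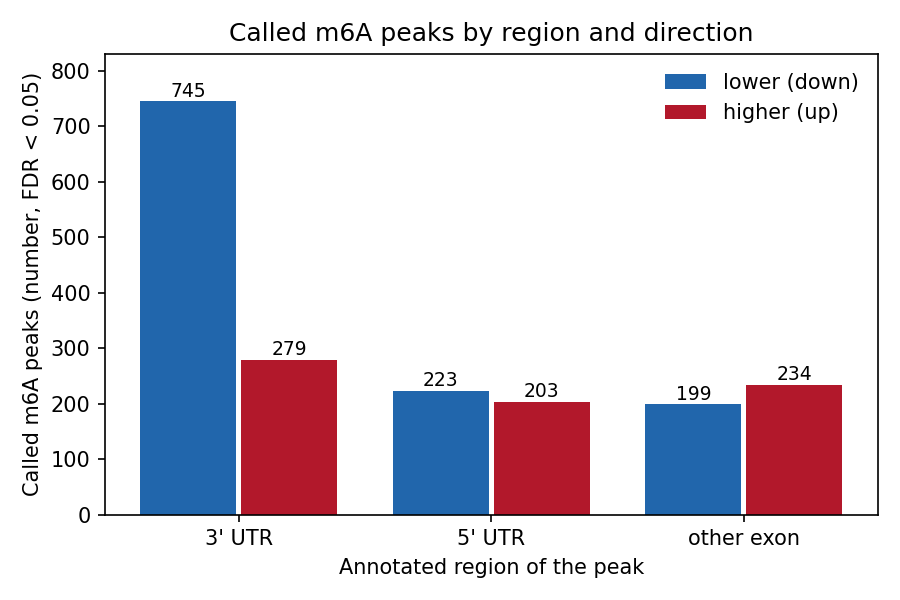
Number of m6A peaks called at an FDR under 0.05 (vertical axis) by annotated region (horizontal axis), with blue bars for peaks lower and red bars for peaks higher in METTL3 knockdown. In the 3' UTR 745 peaks were lower and 279 higher, against 223 and 203 in the 5' UTR and 199 and 234 in other exons.

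The largest decreases were taken among called genes without clone, predicted or pseudogene names, with 1 peak per gene, the one with the smallest p. Within this set the steepest fall was in an exon of U2AF1, the small subunit of the splicing factor that recognises 3' splice sites, at -5.35 (ENSG00000160201, chromosome 21, 43101354 to 43101594, FDR 0.000427 in the authors' deposited table). The higher side held its near-identical copy U2AF1L5, with a 5' UTR peak at 4.72 in the authors' deposited table (ENSG00000275895, chromosome 21, 6493047 to 6493257, FDR 1.18e-07). Reads of this gene pair can be placed on either copy, so both changes are uncertain, and a second U2AF1 peak in the 3' UTR had -0.58 with an FDR of 0.574 in the authors' deposited table. SLC25A46, a mitochondrial outer membrane protein of the solute carrier family, had a lower 5' UTR peak on chromosome 5 (110738027 to 110738956) at -4.28, with an FDR of 0.00269 in the authors' deposited table. PCDH12, a protocadherin, was lower in its 5' UTR at -3.89 with an FDR of 0.0170 in the authors' deposited table, where this peak overlaps a peak assigned to RNF14. Lower exon peaks of the non-coding transcripts DSCR9, SGMS1-AS1 and RPL37A-DT had log2 fold changes of -4.27, -4.13 and -4.03 in the authors' deposited table. Their FDRs were 0.0191, 0.00891 and 0.0417 in the authors' deposited table. Exon peaks assigned to KRT86, DOCK6, CD70 and ZNF263 were lower at -5.09, -4.61, -4.58 and -4.44 in the authors' deposited table, but for these 4 genes the exon named in the annotation belongs to another gene identifier. KRT86, DOCK6 and ZNF263 had FDRs of 0.0355, 0.00229 and 0.0282 in the authors' deposited table. The CD70 and ZNF263 peaks also lie outside the RefSeq bounds of those genes. CD70, a ligand of the tumour necrosis factor family, had an FDR of 0.0479 at this exon (chromosome 19, 6593590 to 6593910), and its 5' UTR peak had an FDR of 0.573 in the authors' deposited table.

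The largest increases followed the same rule. SPP1, which encodes the secreted matrix protein osteopontin, was higher by 5.02 on the log2 scale in a 5' UTR peak (ENSG00000118785, chromosome 4, 87975709 to 87977789, FDR 6.46e-07 in the authors' deposited table). ANPEP, the membrane aminopeptidase CD13, was higher by 4.50 in the 3' UTR (chromosome 15, 89785014 to 89791070, FDR 0.000468 in the authors' deposited table). SLC7A7, a light chain of a cationic amino acid transporter, was higher by 4.45 in an exon (chromosome 14, 22812925 to 22813253, FDR 0.000513 in the authors' deposited table). The matrix protein genes CILP2 and MATN2 were higher in their 3' UTRs by 4.86 and 4.11, with FDRs of 0.00363 and 0.0331 in the authors' deposited table. The keratin-associated KRTAP2-2 was higher in an exon by 4.89, with an FDR of 0.00676 in the authors' deposited table. RFX2, a transcription factor of ciliated cells, had 4.20 with an FDR of 0.0339 in the authors' deposited table, although this peak lies outside the RefSeq bounds of the gene. RGPD6 at 6.87 and MAGEA2B at 5.23 in the authors' deposited table belong to families with near-identical copies and are uncertain for that reason. Their FDRs were 0.0200 and 5.01e-14 in the authors' deposited table. Peaks of this size were few: 31 called peaks had an absolute log2 fold change of at least 4, with 14 lower and 17 higher, and 6 of them were assigned to pseudogenes.

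Gene groups fixed before the data were examined were tested next, with 1 peak per gene, as the share of lower or higher members against all other genes (21 lists, 42 Fisher's exact tests, Benjamini-Hochberg adjusted). Each value below belongs to that peak, and peaks of the same gene that were not called can have the opposite sign. A gene with more peaks has more chances of a call, and the list tests did not account for this. Ribosomal protein genes had a larger share of lower members than the rest: 13 of 22 measured members were lower, 0 higher and 9 not called, against 13.9% lower among the other genes (odds ratio 8.95, adjusted p = 4.65e-05). There were 14 members called when adjusted over the list alone, against 13 over all peaks. RPL13 fell most among these called members, by 0.595 on the log2 scale in a 3' UTR peak (ENSG00000167526, chromosome 16, 89562894 to 89563463, FDR 1e-164 in the authors' deposited table). RPS27A, RPL34 and RPS24 had -0.41, -0.39 and -0.38 in the authors' deposited table. All 15 called peaks of ribosomal protein genes were lower. Subtracting the median shift left 13 of the 15 below 0 at smaller sizes, with RPL13 at -0.36, RPS27A at -0.17, RPL34 at -0.16 and RPS24 at -0.15. The m6A readers, proteins that bind methylated RNA, had 5 of 8 members lower against 14.0% of the other genes (odds ratio 10.3, adjusted p = 0.0293). All 8 were called when adjusted over the list alone, and 6 over all peaks. IGF2BP2 and FXR1, both RNA-binding proteins that regulate stability and translation of mRNA, had -0.53 and -0.47 in their 3' UTRs in the authors' deposited table. YTHDC1, a nuclear reader, had -0.28 in an exon and RBMX -0.26 in its 3' UTR in the authors' deposited table. HNRNPA2B1 was lower at -0.19 in the authors' deposited table but changed sign when the median shift was subtracted. After that subtraction IGF2BP2 had -0.30 and FXR1 -0.24, while YTHDC1 and RBMX were close to 0 at -0.046 and -0.024. YTHDF1, a cytoplasmic reader, was the 1 member that was higher, at 0.23 in the authors' deposited table.

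Chromatin and transcription regulators had a larger share of higher members, with 8 of 29 measured members higher, 2 lower and 19 not called, against 8.18% higher among the other genes (odds ratio 4.27, adjusted p = 0.0293). There were 12 called when adjusted over the list alone and 10 over all peaks, and the 8 higher members ran from 0.21 to 0.90 in the authors' deposited table. SETD2, a histone H3 lysine methyltransferase, and TET3, a DNA demethylation enzyme, were higher in exons at 0.90 and 0.47 in the authors' deposited table. The bromodomain protein BRD3 and the acetyltransferase CREBBP were higher in their 3' UTRs at 0.43 and 0.30 in the authors' deposited table, where an exon peak of CREBBP that was not called had -0.75 (FDR 0.111). KDM5A, a histone demethylase, and NCOR1, a nuclear receptor corepressor, were lower in their 3' UTRs at -0.999 and -0.607 in the authors' deposited table. With p under 0.01 in place of the FDR, the difference from other genes no longer passed (adjusted p = 0.140). The 29 genes held 61 peaks, of which 9 were called higher and 2 lower at the FDR threshold. Of all 10987 peaks, 716 were called higher and 1167 lower.

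The other 18 lists did not differ from the rest of the genes past the threshold after adjustment. Of 5 measured m6A writers and cofactors, RBM15, which recruits the methyltransferase to RNA, was higher at 0.44 in a 5' UTR peak (FDR 3.39e-07 in the authors' deposited table), and METTL14, the binding partner of METTL3, had 0.29 with an FDR of 0.0891. The scaffold proteins ZC3H13 and VIRMA had -0.29 and -0.18 with FDRs of 0.0537 and 0.0813, and METTL16 had -0.20 with an FDR of 0.115, in the authors' deposited table. Of the 10 peaks of these 5 genes, 7 had a negative fold change. All 5 were called when adjusted over the list alone, against 1 over all peaks. The eraser FTO had 0.44 in an exon and -0.57 in the 3' UTR in the authors' deposited table, with FDRs of 0.145 and 0.193. Both FTO peaks passed when adjusted over the list alone, 1 higher and 1 lower, so this gives no direction for the gene. By that count 1 of 1 erasers was called, against 0 over all peaks. Of 14 described METTL3 substrates, 0 were lower and 2 higher, among them the transcription factor SP1 at 0.28 in the authors' deposited table (3 adjusted over the list alone, 2 over all peaks). MYC, in that list, had 5' UTR peaks at -0.41 and 1.35 in the authors' deposited table, with FDRs of 0.316 and 0.455.

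Among cell cycle genes, 4 of 12 were lower and 0 higher (6 adjusted over the list alone, 4 over all peaks; Fisher's exact test, adjusted p = 0.572). These were the replication licensing factor CDC6 at -0.83, the topoisomerase TOP2A at -0.32, the cyclin CCND1 at -0.32 and the mitotic kinase AURKB at -0.30 in the authors' deposited table. Subtracting the median shift left CDC6 at -0.60 and the others close to 0, with TOP2A at -0.086, CCND1 at -0.082 and AURKB at -0.060. All 5 peaks of CCND1 were called lower, from -0.42 to -0.15 in the authors' deposited table, and they lie in 3 separate places on chromosome 11; the weakest, at -0.15, changed sign when the median shift was subtracted. In the MAPK output list, 2 of 8 were lower and 1 higher (5 adjusted over the list alone, 3 over all peaks), with SPRED1, an inhibitor of RAS signalling, at -0.35 and PHLDA1 at 0.42 in the authors' deposited table. With the median shift subtracted, SPRED1 had -0.11 and PHLDA1 0.65. Of 14 genes of PI3K, receptor tyrosine kinase and RAS signalling, 3 were lower (5 adjusted over the list alone, 3 over all peaks). PIK3CB, a catalytic subunit of PI3K, had -0.47 in its 3' UTR in the authors' deposited table, and -0.24 with the median shift subtracted. MET, the hepatocyte growth factor receptor, had -0.19 in the authors' deposited table and changed sign when the median shift was subtracted. Of 13 glycolysis and hypoxia genes, 3 were lower and 1 higher (4 adjusted over the list alone, 4 over all peaks). The mitophagy receptor BNIP3 had -0.98, the hexokinase HK1 -0.57, the phosphofructokinase PFKP -0.55 and the lactate transporter SLC16A1 1.53 in the authors' deposited table.

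Genes of epithelial-mesenchymal transition and matrix remodelling went both ways, with 2 of 11 lower and 3 higher (8 adjusted over the list alone, 5 over all peaks). ITGB1, the beta 1 integrin that binds extracellular matrix, was higher by 1.96 in a 3' UTR peak (ENSG00000150093, chromosome 10, 32900408 to 32900617, FDR 3.16e-60 in the authors' deposited table). A separate 3' UTR peak of ITGB1 (chromosome 10, 32901215 to 32901305) was higher by 1.72 with an FDR of 2.00e-11 in the authors' deposited table. TGFB1, the growth factor, and TWIST2, a transcription factor, were higher at 0.70 and 0.70 and the membrane metalloproteinase MMP14 was lower at -0.85 in the authors' deposited table. Another called peak of TGFB1, in a separate place, was higher at only 0.18 in the authors' deposited table. Of 17 Wnt and Hippo genes, TEAD1, a DNA-binding partner of YAP, was lower at -0.60, and the Wnt receptor FZD2 and the scaffold AXIN1 were higher at 0.35 and 0.28 in the authors' deposited table (3 adjusted over the list alone, 3 over all peaks). Of 6 measured genes in the Hedgehog list, KIF7, a regulator of GLI proteins, and STEAP3 were higher at 0.52 and 0.29 in the authors' deposited table (4 adjusted over the list alone, 2 over all peaks). STEAP3 and STEAP2 are metalloreductases that this list holds beside the pathway's components, so KIF7 was the only called component. A shorter KIF7 peak within the called one was not called and had -0.24 (FDR 0.143) in the authors' deposited table. STEAP2 had 0.80 with an FDR of 0.277 in the authors' deposited table. Of 6 thyroid differentiation genes, the thyroid hormone receptor THRA was lower at -0.80 and the transcription factor GLIS3 higher at 0.67 in the authors' deposited table (3 adjusted over the list alone, 2 over all peaks).

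Of 11 apoptosis and p53 target genes, MCL1 and BCL2L1, both inhibitors of apoptosis, were higher at 0.20 and 0.14 in the authors' deposited table (3 adjusted over the list alone, 2 over all peaks). Of 7 genes of the integrated stress and unfolded protein responses, PSAT1, an enzyme of serine synthesis, was lower at -0.41 in the authors' deposited table, and DNAJB1, a heat shock co-chaperone, was lower at -0.13 but changed sign when the median shift was subtracted (4 adjusted over the list alone, 2 over all peaks). PSAT1 had -0.17 after the same subtraction. Of 10 interferon response genes, the RNA-editing enzyme ADAR was higher at 0.25 in the authors' deposited table (1 adjusted over the list alone, 1 over all peaks). CD70 was the 1 called gene of 2 measured immune checkpoint genes (1 adjusted over the list alone, 1 over all peaks). The NF-kB list had 3 measured members and the fibroblast and endothelial markers 3, with 0 called over all peaks and 0 adjusted over the list alone. Leukocyte markers had 2 measured members, with 0 called over all peaks and 1 adjusted over the list alone. The plot of list members shows each gene's log2 fold change for the lists with at least 6 measured members.

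**Figure D2:**
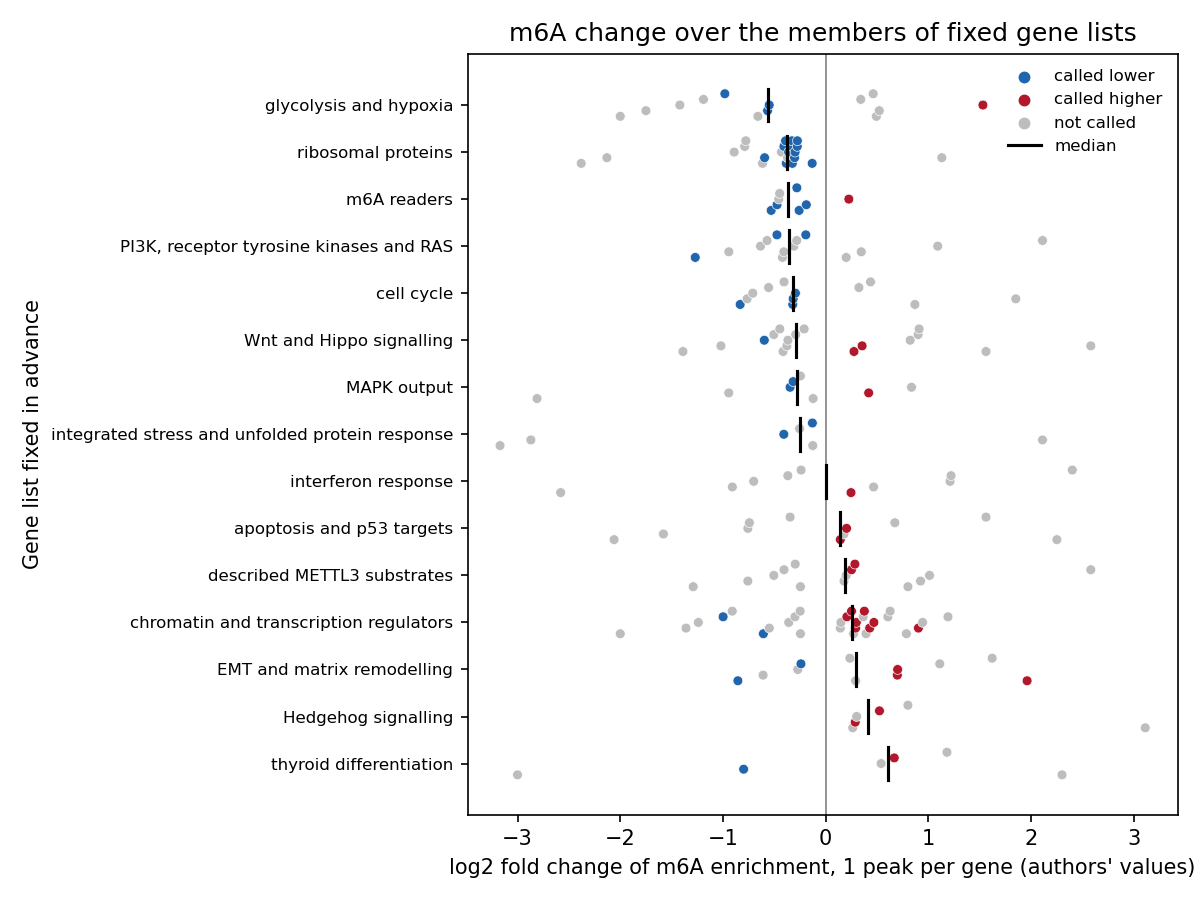
Authors' log2 fold change of m6A enrichment, METTL3 knockdown relative to control (horizontal axis), with 1 point per gene for lists of at least 6 measured members (vertical axis), blue where called lower, red where called higher, grey where not called, and a black bar at each list's median. Ribosomal proteins show 13 blue and 0 red points and chromatin and transcription regulators 2 blue and 8 red; with the median shift of -0.24 subtracted, 12 of the 13 called ribosomal protein genes stay lower and the 2 and 8 chromatin regulators keep their directions.

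Annotation terms in the authors' deposited table were tested in the same way. Genes that bind or process RNA were lower far more often than others: 144 of 490 genes of the term RNA binding were lower, 29.4% against 13.6% of the other annotated genes (Fisher's exact test, adjusted p = 4.72e-14 over 1974 tests of 987 gene ontology terms), and 36 were higher. Among these, ERI1, an exonuclease of histone mRNA, had -1.13 in its 3' UTR in the authors' deposited table. A peak assigned to the cold-inducible RNA-binding protein CIRBP had -2.12 in the authors' deposited table but lies outside the RefSeq bounds of that gene. Translation genes had 30 of 79 lower and 4 higher, including the initiation factors EIF2B3 at -1.24 and EIF3F at -0.60 and the release factor GSPT1 at -0.58 in the authors' deposited table. RNA splicing genes had 35 of 110 lower and 7 higher, among them USP39, a factor of spliceosome assembly, at -0.58 in the authors' deposited table. Genes of ribonucleoprotein complexes had 23 of 49 lower and 2 higher, with the splicing regulator HNRNPL at -0.99 in the authors' deposited table. Protein transport genes had 59 of 236 lower and 15 higher, including the nuclear import carrier HIKESHI at -3.01 and the retromer subunit VPS29 at -1.57 in the authors' deposited table. In all, 29 gene ontology terms passed, 28 with more lower genes and 1 with more higher genes. Terms share genes and are not separate results: RPL13 and RPL34 are lower members of structural constituent of ribosome, ribosome, viral transcription and cytosolic large ribosomal subunit. The median shift was not subtracted for the term tests. Lower was also set against higher among called genes alone, and 20 of the 28 terms passed there, including RNA binding (Fisher's exact test, adjusted p = 2.00e-06 over the 29 terms that had passed). The 28 terms had been picked for their excess of lower genes in the same calls, which favours passing, so this count is no independent support. Among the 8 that did not pass were mRNA binding (adjusted p = 0.0555), mRNA transport (0.0735), mRNA 3'-UTR binding (0.112), mRNA splicing via the spliceosome (0.142) and rRNA binding (0.271).

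Of the KEGG pathways, 2 passed over 470 tests of 235 terms. The ribosome pathway had 16 of 28 genes lower and 0 higher, 57.1% against 16.1% of other genes (Fisher's exact test, adjusted p = 0.000499). The pathway named herpes simplex virus 1 infection had fewer lower genes than the rest, 17 of 242 (7.02% against 17.7%, adjusted p = 0.00141), and 24 higher. Most of its members here, 187 of 242, were zinc finger genes by name, a family of DNA-binding transcription factors, of which 10 were lower and 20 higher. The term with more higher genes was nucleic acid binding, with 81 of 620 higher against 8.56% of the others (adjusted p = 0.0326) and 80 lower; 351 of its 620 genes were zinc finger genes by name. Its largest increases after U2AF1L5 were the zinc finger genes ZDBF2 at 3.31 and SALL4 at 3.16 and the DNA repair nuclease FAN1 at 2.52 in the authors' deposited table.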

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

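The tests chosen only after the result was seen were the region comparison under every setting other than 1 peak per gene (a larger fold change, p under 0.01, centring and all peaks among them), the centred values of single genes, the Benjamini-Hochberg adjustment over these peaks, 1 peak per overlapping place, the sets without ribosomal protein genes and pseudogenes or within gene bounds, and the term tests at p under 0.01. An absolute log2 fold change of at least 1 left 165 lower and 149 higher peaks, 52.5% lower (exact binomial p = 0.397), and region odds ratios of 1.20 for the 3' UTR, 0.923 for the 5' UTR and 0.880 for other exons (adjusted p = 0.882 for each). Fewer peaks enter there, and otherwise the cause was not tested. Under that threshold 23 of the 64 named genes were still called and 41 were not. With p under 0.01, which calls more peaks, 0 lists had more higher genes, since the chromatin and transcription regulators, still at 27.6% higher, had an adjusted p of 0.140 against 10.8% of other genes, in place of 8.18%. Centring on the median of all peaks turned DNAJB1 to 0.11 and MET to 0.041 and left the direction of the other 62. The cause follows from the subtraction of -0.24. The share of lower peaks was 63.0% with 1 peak per gene, and 55.3% of all peaks whatever their p were lower. Centring removes the overall balance of signs, so its 53.9% (1015 lower and 867 higher) is no test of the excess. Benjamini-Hochberg over these peaks called 1644 lower and 1020 higher. No paired analysis was possible because the table holds no values per library; for the same reason leaving out each library, count and expression filters and the expression alternatives were not run, nor were regions from a reference annotation or an enrichment filter. With no depth, small changes passing the threshold cannot be separated from well covered peaks.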

Other observations

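The tests chosen only after the result was seen were the comparisons of 3' and 5' UTR peaks within genes and the comparison of ribosomal protein peaks with other peaks of the same size. The mitochondrial genes were singled out after their values were seen. Of 6 peaks on mitochondrial genes, 5 were called and all 5 were higher: MT-CYB at 1.14, MT-ND2 at 0.59, MT-CO2 at 0.55 and MT-ND3 at 0.43 in the authors' deposited table, with a peak assigned to MT-ND4 at 0.61 whose exon belongs to another gene identifier. MT-ND1 had -0.18 with an FDR of 0.226 in the authors' deposited table. Of the 1878 called nuclear peaks, 37.9% were higher.

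The 20 peaks with the smallest p, in 18 separate places, held 18 lower and 2 higher peaks with a median absolute log2 fold change of 0.40. Among them were 6 peaks assigned to ribosomal protein genes and 4 assigned to pseudogenes, such as RPL13AP7 at -2.72 and HMGB1P5 at -2.21 in the authors' deposited table, which share sequence with their parent genes RPL13A and HMGB1. Other peaks in this set are labelled 3' UTR but assigned to the small RNA genes SNORA31B, SNORA66 and MIR1184-1. The assigned gene therefore need not be the transcript that carries the peak, and counts by gene name can miss members. TMEM185A, a transmembrane protein gene, was lower at -2.85 in its 3' UTR, and the chaperone DNAJB6 at -0.88, in the authors' deposited table. Higher peaks in this set were those of ITGB1 and of BANF1, a chromatin-binding protein of the nuclear envelope, at 0.36 in the authors' deposited table.

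Called 3' UTR peaks were lower more often than called 5' UTR peaks. Whether different genes carrying the 2 kinds of peak make this difference stays open. Of 36 genes with a called peak in both UTRs, 12 had the 3' UTR lower and the 5' UTR higher and 2 the opposite (exact two-sided sign test, p = 0.0129), but the 3' UTR value was below the 5' UTR value in only 20 of the 36 (exact two-sided sign test, p = 0.618), and after centring the counts were 13 and 4 (p = 0.0490). Ribosomal protein genes and pseudogenes did not make the difference, since the odds ratio was 2.43 without them (Fisher's exact p = 1.96e-13) and 2.43 with them. Depth may still contribute, and a tilt in coverage along transcripts between libraries was not tested, nor was a biological explanation. Over 3 equal groups of the called UTR peaks by genomic span, the odds ratios were 3.94, 1.51 (Fisher's exact p = 0.0544) and 2.13. Spans include introns and reach 280736 bases in the widest group. They are a poor stand-in for depth, so this split cannot decide the question.

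All 15 called ribosomal protein peaks were lower, with absolute log2 fold changes from 0.13 to 0.59. Of the other called peaks of this size, 744 of 1180 were lower (63.1%, Fisher's exact p = 0.00174), but peaks were matched on fold change and not on depth, so a higher depth on these abundant transcripts may still contribute. Their place in 3' UTRs alone would give the share of other 3' UTR peaks, and 12 of 12 ribosomal protein 3' UTR peaks were lower against 733 of 1012 others (72.4%, Fisher's exact p = 0.0438, close to the threshold). Reads shared with ribosomal protein pseudogenes, a change of these transcripts in the input libraries and an effect of METTL3 on them stay open, since no values per library were used.

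Peaks of 1 gene tended to change in the same direction. Of 130 genes with at least 2 called peaks that do not overlap, 86 (66.2%) had peaks of 1 direction and 44 had both. Shuffling the directions among peaks of the same region gave a median of 66 such genes and at most 88 in 10000 shuffles. A share of 0.0003 of the shuffles had as many (one-sided), so chance was an unlikely source under this shuffle, though it is not excluded. The shuffle treats called peaks of 1 region as exchangeable. A change shared by a whole transcript, in its m6A or in its input level, was not tested.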
